A study of Homo sapiens with 8 samples.

How the data were processed

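The samples were MCF-7 cells, an established human breast cancer line that expresses the estrogen receptor and grows in response to estradiol (E2). Per the labels' protocols, cells were transfected with 20 nM of a control siRNA (siGL3, against the GL3 luciferase, which human cells lack) or of an siRNA against ERK5, the kinase encoded by MAPK7. After 72 h they received 10 nM E2 or 0.1% ethanol as vehicle for 24 h. Biotin-labelled cRNA was made from 10 µg of total RNA and hybridised to Affymetrix short-oligonucleotide arrays, per the labels. The design has 4 groups of 2 arrays: control siRNA with vehicle, control siRNA with E2, ERK5 siRNA with vehicle and ERK5 siRNA with E2. Groups and replicate numbers were taken from the sample titles.

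The authors deposited intensity values on a linear scale, 1 per probe set and array, for 22283 probe sets. How probe signals were summarised and scaled is not given in the sources used here. The deposited intensity values ran from 4.71 to 44577, array medians lay between 8.82 and 9.27, and the lowest value was shared by all 8 arrays, so the arrays were taken to be on a common scale already. Between 26.5% and 29.8% of probe sets held that lowest value on an array, where values have no order, and about 55% lay below 16. A probe set near this floor can show a rise, but little of a fall. The number of arrays limits the precision.

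Names came from the annotation table of the platform record, which is the first version of this array design, while the series describes the later version. The probe set names matched. Of the probe sets other than the 68 controls, 19065 had 1 gene, 1043 had several and 2107 had none. Symbols were updated through Entrez identifiers (19053 probe sets matched) with RefSeq names from assembly GRCh38.p14, used for names only. No genome build is named for the values, so no coordinates are given. Each gene was represented by the probe set with the highest mean over all arrays among those with 1 gene, which left 11963 genes. Controls and probe sets with several genes or none were left out.

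The unit and design decided the test. Values were transformed as log2(intensity + 16), with no further normalization. All fold changes are on this scale, which understates the change of dim genes. A linear model with a mean for each of the 4 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with default settings), so the groups shared an estimate of the spread with 4 residual degrees of freedom. The prior estimated over genes added only 0.44 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were the effect of E2 with each siRNA, the effect of ERK5 siRNA with each treatment, the difference between the E2 effects (ERK5 siRNA minus control siRNA), and both average effects. MAPK7 was tested besides with an exact two-sided permutation test of 4 against 4 arrays.

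The tests, 15 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover estrogen-induced genes, estrogen-lowered genes, DNA replication and S phase, G2/M and mitosis, actin cytoskeleton, invasion and epithelial-mesenchymal transition, the ERK5 and ERK pathway, interferon response, p53 targets and growth arrest, cholesterol synthesis, unfolded protein response, luminal epithelial identity, basal epithelial markers, fibroblast and endothelial markers, and immune cell markers. They hold 480 entries, of which 431 were measured. Lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 75 tests of list and comparison. Camera with an estimated correlation and fry were alternatives. Named genes are MAPK7, ESR1 and CFL1 always. For E2 with control siRNA, ERK5 siRNA with E2 and the difference they are also the 10 called genes with the largest rise and the 10 with the largest fall whose replicates do not overlap. For the other comparisons they are 6 and 6. For each list described they are up to 4 members with the smallest p. List members that make up a count of 5 or fewer are also named, and were chosen after their values were seen.

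The E2 response left with ERK5 siRNA was measured over genes called for the average E2 effect, which favours neither siRNA, as an orthogonal slope through 0 of one E2 log2 fold on the other. Overlaps between comparisons that share arrays were set beside 50 simulations of unchanged genes and beside the value for independent lists. The model was tested on simulated data with the real gene means and spreads, 11963 genes and 200 changed genes. The changed genes were drawn from those with a mean intensity of at least 16, so the recovery of dimmer genes was not measured. For E2 with control siRNA it called 53 of 100 genes changed by 1 on the log2 scale and 87 of 100 changed by 2, with 11 unchanged genes called. For the difference between E2 effects it called 28 of 100 and 61 of 100, with 5 unchanged genes called.

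Alternatives were quantile or median normalization, all probe sets or the mean of a gene's probe sets, leaving out probe sets of lower specificity, keeping only the 8972 or 5981 brightest genes, eBayes with trend and robust, the replicate number as a block, only the arrays compared, pseudocounts of 1 and 64, and each array left out in turn. For a comparison of 2 groups, leaving out an array of another group keeps every fold and changes only the estimate of the spread. Either array of such a group gives the same fit, so the 8 fits with 1 array left out are not all distinct. A fit without pseudocount and a fit without both E2 arrays of low ribosomal RNA signal were added after the data were seen.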

Results

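Expression was measured on 8 arrays of MCF-7 breast cancer cells that carried a control siRNA or an siRNA against ERK5, a mitogen-activated protein kinase, and were then given vehicle or estradiol (E2), 2 arrays per group. The design asks what E2 does to gene expression, what ERK5 siRNA does with and without E2, and whether the response to E2 differs when ERK5 is targeted. The series relates ERK5 and cofilin to estrogen receptor-driven transcription, the actin cytoskeleton and invasiveness. Upper-quartile intensities lay between 108 and 116.2 on all arrays. Replicates correlated at 0.9958 or more across genes, which are not independent replicates. In the first 2 principal components, the first (53.8% of the variance) separated E2 from vehicle arrays and the second (22.8%) separated the siRNAs. The signal of an 18S ribosomal RNA control was 153 on array 1 of control siRNA with E2 and 231 on array 2 of ERK5 siRNA with E2, against 613 to 2340 on the others. A hybridisation control (bioB) was brightest with ERK5 siRNA and vehicle, at 365 and 307, against 207 to 307 elsewhere. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

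The siRNA's target could not be followed. MAPK7, which encodes ERK5, lay between 5.9 and 7.14 on its brighter probe set and between 4.83 and 5.17 on the other, close to the lowest value of the arrays. The ERK5 siRNA arrays differed from the control siRNA arrays by -0.0202 and -0.0059 on the log2 scale (exact two-sided permutation p = 0.429 and 0.571 over 70 splits, 4 arrays against 4). The single array above 5.928 on the brighter probe set was vehicle array 2 of control siRNA. Without vehicle array 1 of control siRNA, limma gave MAPK7 adjusted p = 0.00763 for the average siRNA effect (-0.0396), where all other arrays hold 5.905 and leave no spread. The loss of the transcript was not detectable at this signal, and the groups rest on the labels. ESR1, the estrogen receptor, fell with E2 from 7398 ± 529 to 3598 ± 362 (SD, n = 2) with control siRNA and from 8490 ± 612 to 4333 ± 4.23 with ERK5 siRNA (limma, log2 fold -1.04 and -0.97, adjusted p = 0.0137 and 0.0186). Its call with control siRNA was lost without vehicle array 1 of control siRNA (adjusted p = 0.0544), and that with ERK5 siRNA without E2 array 1 or 2 of ERK5 siRNA (0.0735 and 0.0828). The ERK5 siRNA did not move ESR1 past the threshold with vehicle (0.20 ± 0.098 SE, adjusted p = 0.505) or with E2 (0.27 ± 0.098, adjusted p = 0.324), and with the mean of its probe sets the log2 fold in vehicle was -0.103. CFL1, the gene of the actin-severing protein cofilin, was bright in all groups, with means from 8938 to 10440. Its log2 folds with ERK5 siRNA were 0.05 ± 0.088 with vehicle and 0.05 ± 0.088 with E2 and passed no test (limma, adjusted p = 0.964 and 1). Without vehicle array 1 of control siRNA the CFL1 log2 fold in vehicle was -0.071.

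With control siRNA, E2 raised classical estrogen target genes and genes of DNA replication, and lowered genes of the estrogen-lowered and luminal lists. CXCL12, a chemokine, rose from 52.29 ± 13.8 to 846.3 ± 54.2 (log2 fold 3.67 ± 0.159 SE, adjusted p = 0.00331), and TFF1, a secreted trefoil peptide, rose from 870.9 ± 55.4 to 5417 ± 287 (2.62 ± 0.088, adjusted p = 0.00222). The other large rises, with log2 folds from 3.20 down to 2.77, were those of PLAC1, SLC7A11 (the cystine transporter), MYBL1, PRSS23, NPY1R, PMAIP1, CA12 (a carbonic anhydrase), IL17RB and TPD52L1. FBN2, a fibrillin of the extracellular matrix, fell from 518.5 ± 23.5 to 36.11 ± 0.501 (-3.36 ± 0.093, adjusted p = 0.00182). ACKR3 (a scavenger receptor of CXCL12), IL1R1, EFEMP1, STON1, ABCC5, NBEA, BIK (which promotes apoptosis), SLC24A3 and BAMBI fell by log2 folds from -3.21 to -2.32. Of the 20 genes with the largest changes, 19 stayed called in every fit that left out 1 array, all but SLC24A3 (adjusted p up to 0.0985). In total 871 of 11963 genes were called, 498 higher and 373 lower, and 270 changed at least 2-fold. The 2-fold count was 128 to 217 when 1 array was left out, lowest without E2 array 1 of control siRNA. It was 39 without both E2 arrays of low ribosomal RNA signal. The count of all calls was 460 without vehicle array 1 of control siRNA, 408 and 463 without E2 array 1 or 2 of control siRNA, 558 without either vehicle array of ERK5 siRNA, 377 without either E2 array of ERK5 siRNA, and 204 without both E2 arrays of low ribosomal RNA signal. The balance of directions turned without vehicle array 1 or 2 of control siRNA, to 188 higher and 272 lower and to 352 higher and 469 lower. It moved the other way without E2 array 1 or 2 of control siRNA (267 higher and 141 lower, and 328 higher and 135 lower) and without both arrays of low ribosomal RNA signal (154 higher and 50 lower).

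Among estrogen-induced genes, 23 of 37 measured members rose and none fell, with 30 called when adjusted over the list alone (median log2 fold 1.03, camera adjusted p = 3.13e-22). In the DNA replication list 20 of 37 rose and none fell, with 33 called when adjusted over the list alone (median 0.76, adjusted p = 1.64e-21). MCM2, a subunit of the replicative helicase, rose from 407.8 to 945.2, MCM5 from 223.2 to 533.6, CDC45 from 37.24 to 91.77 and GINS2 from 731.1 to 1325. Both lists kept their call with an estimated correlation, but at a camera adjusted p of only 0.0236 each. Of the estrogen-lowered genes 12 of 20 fell and none rose, with 14 called when adjusted over the list alone, 13 of them lower (median -1.04, adjusted p = 2.34e-10, but adjusted p = 0.0514 with an estimated correlation), among them IL1R1, BIK, EFNA1 and CCNG2. In the luminal identity list 9 of 19 fell and XBP1 rose, with 12 called when adjusted over the list alone, 10 of them lower (adjusted p = 2.12e-06, and adjusted p = 0.0533 with an estimated correlation). CD24 fell from 9311 to 3187 and GATA3, a luminal transcription factor, from 12280 to 7732. In the G2/M and mitosis list 6 of 38 rose, with 15 called when adjusted over the list alone (median 0.43, adjusted p = 2.34e-10, and adjusted p = 0.0514 with an estimated correlation), among them MAD2L1, CDK1, FOXM1 and CDCA8. In the unfolded protein response list 4 of 24 rose (ASNS, ATF3, ATF4, XBP1), with 6 called when adjusted over the list alone, 5 of them higher (adjusted p = 0.00132, and adjusted p = 0.314 with an estimated correlation). ASNS, asparagine synthetase, rose from 412.3 to 2206. CCNG2 and CD24 lost their calls without E2 array 1 and without E2 array 2 of control siRNA (adjusted p = 0.0549 and 0.0514), and CDK1, FOXM1, CDCA8, ASNS, ATF3, ATF4 and XBP1 lost theirs in 4 to 6 of the 8 fits that left out 1 array, with adjusted p up to 0.112.

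**Figure D1:**
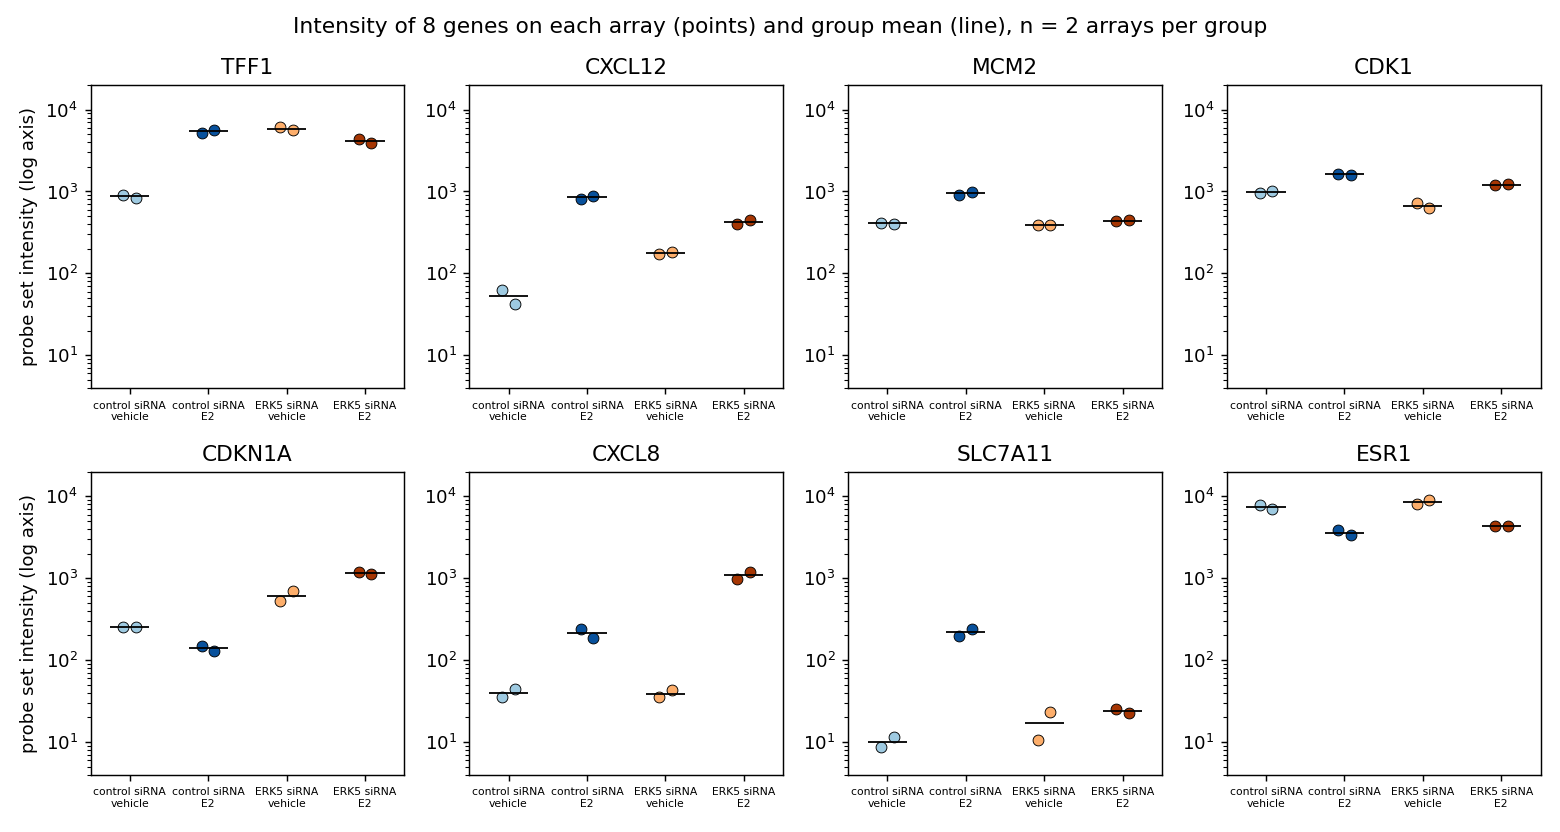
Probe set intensity (log axis) of 8 genes on each array; points are arrays, lines are means of the 2 arrays of a group. TFF1 is near 5874 with ERK5 siRNA and vehicle, against 870.9 with control siRNA and vehicle, MCM2 rises with E2 to 945.2 with control siRNA and lies at 441.9 with ERK5 siRNA and E2, and CXCL8 reaches 1084 with ERK5 siRNA and E2.

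With ERK5 siRNA, E2 raised genes of the mitosis and p53 lists and lowered genes of the luminal list. CXCL8 (interleukin-8) rose from 39.1 ± 5.79 to 1084 ± 165 (SD, n = 2; log2 fold 4.32 ± 0.189 SE, limma adjusted p = 0.00341). The chemokines CCL2, CCL20 and CXCL10 rose by 3.44, 3.41 and 2.96, and CAV1 (caveolin) and IL17RB by 2.92 and 2.91. ACKR3 fell from 647.8 ± 67.7 to 57.42 ± 12.1 (-3.18 ± 0.142, adjusted p = 0.00341), and BAMBI, RETREG1, DEGS1, ABCC5 and EFEMP1 fell by log2 folds from -2.58 to -2.35. All but DEGS1 and EFEMP1 of these 12 genes stayed called in every fit that left out 1 array. In total 646 genes were called, 351 higher and 295 lower, and 184 changed at least 2-fold. The 2-fold count was 91 to 163 when 1 array was left out, lowest without either E2 array of ERK5 siRNA. It was 29 without both arrays of low ribosomal RNA signal. With quantile normalization 315 genes were higher and 319 lower, and with only the arrays compared 25 and 27. The count of all calls was 426 without either vehicle array of control siRNA, 305 without either E2 array of control siRNA, 1082 without vehicle array 2 of ERK5 siRNA, 364 without E2 array 2 of ERK5 siRNA, and 148 without both arrays of low ribosomal RNA signal. More genes were lower than higher without vehicle array 1 or 2 of ERK5 siRNA (275 higher and 620 lower, and 341 higher and 741 lower). The share of higher genes grew without E2 array 1 or 2 of ERK5 siRNA (314 higher and 124 lower, and 252 higher and 112 lower) and without both arrays of low ribosomal RNA signal (117 higher and 31 lower).

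Of the G2/M and mitosis genes 10 of 38 rose and none fell, with 30 called when adjusted over the list alone (median log2 fold 0.605, camera adjusted p = 1.22e-16). KIF20A, a mitotic kinesin, rose from 136.7 to 283.8, AURKA from 393.9 to 666.4 and CDK1 from 671.8 to 1214. Of the p53 targets 6 of 19 rose and none fell, with 7 called when adjusted over the list alone (median 0.34, adjusted p = 2.12e-06). FAS, a death receptor, rose from 35.93 to 150.4, and BAX, a pro-apoptotic protein, from 429.7 to 666.9. Of the luminal identity genes 9 of 19 fell and none rose, with 13 called when adjusted over the list alone (median -0.54, adjusted p = 2.14e-10), among them CD24, MUC1, SPDEF and ESR1. The G2/M, p53 and luminal lists kept their call with an estimated correlation (camera adjusted p = 0.0275, 0.0311 and 0.0275). Of the estrogen-induced genes 9 of 37 rose and NHERF1 and XBP1 fell, with 22 called when adjusted over the list alone, 16 of them higher (median 0.41, adjusted p = 0.000478, but adjusted p = 0.0844 with an estimated correlation). CA12 rose from 347.9 to 2603. Of the estrogen-lowered genes 8 of 20 fell and ID1 rose, with 11 called when adjusted over the list alone, 9 of them lower (adjusted p = 3.57e-06, and adjusted p = 0.103 with an estimated correlation). In the DNA replication list only TYMS, thymidylate synthase, rose among 37, over all genes and when adjusted over the list alone (median 0.17, adjusted p = 0.00177, and adjusted p = 0.217 with an estimated correlation). That list lost its call without E2 array 1 of ERK5 siRNA (median 0.126, adjusted p = 0.137). KIF20A, AURKA, CDK1, FAS, BAX, CD24, MUC1, SPDEF, ESR1 and TYMS lost their calls in 2 to 6 of the 8 fits that left out 1 array, with adjusted p up to 0.107.

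In vehicle, ERK5 siRNA was accompanied by higher estrogen-induced genes and lower mitotic genes. TFF1 stood at 5874 ± 321 against 870.9 ± 55.4 with control siRNA (SD, n = 2; log2 fold 2.73 ± 0.088 SE, limma adjusted p = 0.00412). TFF3, another trefoil peptide, stood at 462.7 ± 83.3 against 80.41 ± 12.4, and RET, a receptor tyrosine kinase, at 296.5 ± 63.8 against 51.99 ± 5.88. PMAIP1, VDR (the vitamin D receptor) and AKR1C2 were higher by log2 folds of 1.81, 1.62 and 1.54. FAM3C fell from 200.7 ± 25.3 to 29 ± 2.03 (-2.26 ± 0.117, adjusted p = 0.0101), FBN2 by a log2 fold of -2.26, and NPM3, RND3, TUBA1A and ANXA3 by -2.14 to -1.63. TFF1, FAM3C and FBN2 stayed called in every fit that left out 1 array, and the other 9 genes did not, with adjusted p up to 0.105. In total 209 genes were called, 91 higher and 118 lower, and 57 differed at least 2-fold. The E2 arrays, among them both of low ribosomal RNA signal, lie outside this comparison. Leaving them out keeps every fold and changes only the estimate of the spread. The 2-fold count was 11 to 79 when 1 array was left out, lowest without either E2 array of control siRNA. The count of all calls was 434 without vehicle array 2 of control siRNA, 606 and 906 without vehicle array 1 or 2 of ERK5 siRNA, 45 without either E2 array of control siRNA and 56 without either E2 array of ERK5 siRNA. It was 0 with limma without both arrays of low ribosomal RNA signal, where 1315 genes had an unadjusted p under 0.05, against 1723 with all arrays. More genes were higher than lower without vehicle array 1 or 2 of ERK5 siRNA (456 higher and 150 lower, and 648 higher and 258 lower). The share of lower genes grew without vehicle array 1 or 2 of control siRNA (49 higher and 140 lower, and 125 higher and 309 lower).

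Of the estrogen-induced genes 9 of 37 were higher and none lower, among them TFF1, AGR2, NHERF1 and TFF3, with 15 called when adjusted over the list alone, 14 of them higher (median 0.45, camera adjusted p = 5.69e-13). AGR2, a protein disulfide isomerase, stood at 16840 against 6850. Of the G2/M and mitosis genes 3 of 38 were lower (AURKA, KIF20A, PRC1), with 29 called when adjusted over the list alone (median -0.67, adjusted p = 5.33e-22). CDK1 had means of 984.7 with control and 671.8 with ERK5 siRNA (limma adjusted p = 0.0568). Both lists kept their call with an estimated correlation (camera adjusted p = 0.0236 each). Of the p53 targets 3 of 19 were higher (BAX, CDKN1A, GADD45A), with 7 called when adjusted over the list alone, 5 of them higher (adjusted p = 0.00551, but adjusted p = 0.103 with an estimated correlation). That list lost its call without vehicle array 2 of ERK5 siRNA (adjusted p = 0.111). The DNA replication list (no member called, also when adjusted over the list alone, 12 of 37 at an unadjusted p under 0.05, median -0.10, adjusted p = 0.0181), the cholesterol synthesis list (no member called, also when adjusted over the list alone, 3 of 18 at an unadjusted p under 0.05, median -0.04, adjusted p = 0.0323) and the unfolded protein response list (XBP1 and SEL1L higher, also when adjusted over the list alone, median 0.13, adjusted p = 0.0221) lost their calls with an estimated correlation, with adjusted p = 0.291, 0.187 and 0.429. They also lost them without vehicle array 1 of control siRNA (adjusted p = 0.216 for DNA replication and 0.133 for cholesterol synthesis), vehicle array 2 of control siRNA (0.0568 for the unfolded protein response), vehicle array 1 of ERK5 siRNA (0.135 for DNA replication) and vehicle array 2 of ERK5 siRNA (0.237 for cholesterol synthesis and 0.65 for the unfolded protein response). TFF3, AURKA, KIF20A, PRC1, BAX, CDKN1A, GADD45A, XBP1 and SEL1L lost their calls in 2 to 8 of the 8 fits that left out 1 array, with adjusted p up to 0.14.

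With E2, ERK5 siRNA was accompanied by higher p53 targets and by lower genes of the DNA replication and mitosis lists. CCL20 stood at 354.4 ± 68.5 against 19.53 ± 0.16 with control siRNA (SD, n = 2; log2 fold 3.37 ± 0.232 SE, limma adjusted p = 0.0188), and CDKN1A, the cell-cycle inhibitor p21, at 1155 ± 48.6 against 139.5 ± 14 (2.92 ± 0.146, adjusted p = 0.0139). CXCL8, AKR1C2, CROT, CXCL10, CXCL1, GPRC5A, H2BC12 and CXCL2 were higher by log2 folds from 2.27 to 1.56. NPM3 stood at 72.83 ± 2.08 against 519.4 ± 2.93 (-2.59 ± 0.163, adjusted p = 0.0152), and SLC7A11 at 24.18 ± 1.83 against 221 ± 30.6 (-2.56 ± 0.213, adjusted p = 0.0228). NUPR1 (a stress-response regulator), FAM3C, SLC7A5 and SLC1A4 (amino acid transporters), ACTA2 (smooth muscle actin), PCK2, ME2 and POLA2 were lower by log2 folds from -2.35 to -1.35. Of these 20 genes 7 stayed called in every fit that left out 1 array (CDKN1A, AKR1C2, CROT, CXCL2, NPM3, FAM3C, ACTA2), and the others reached adjusted p up to 0.145. In total 209 genes were called, 95 higher and 114 lower, and 58 differed at least 2-fold. The 2-fold count was 22 to 40 when 1 array was left out, lowest without E2 array 2 of control siRNA. It was 10 without both arrays of low ribosomal RNA signal. With all probe sets, 76 probe sets were higher and 74 lower, and with only the arrays compared 8 genes were higher and 6 lower. The count of all calls was 88 without either vehicle array of control siRNA, 315 without E2 array 1 of ERK5 siRNA and 195 without both arrays of low ribosomal RNA signal. The balance turned to 227 higher and 88 lower without E2 array 1 of ERK5 siRNA, to 158 higher and 62 lower without E2 array 2 of ERK5 siRNA, and to 82 higher and 79 lower without either vehicle array of ERK5 siRNA. It moved further to lower genes without E2 array 1 or 2 of control siRNA (60 higher and 135 lower, and 45 higher and 152 lower), and was 94 higher and 101 lower without both arrays of low ribosomal RNA signal.

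Of the DNA replication genes 10 of 37 were lower and none higher, with 32 called when adjusted over the list alone (median log2 fold -0.67, camera adjusted p = 1.23e-27). MCM2 stood at 441.9 against 945.2, MCM5 at 243.3 against 533.6, CDC45 at 43.55 against 91.77 and GINS2 at 778 against 1325. Of the G2/M and mitosis genes MAD2L1, a spindle checkpoint protein, was lower, with 19 of 38 called when adjusted over the list alone (median -0.45, adjusted p = 5.81e-16). Of the p53 targets 6 of 19 were higher, among them BAX, CDKN1A, GADD45A and ZMAT3, with 11 called when adjusted over the list alone, 10 of them higher (median 0.65, adjusted p = 3.3e-11). The DNA replication, G2/M and p53 lists kept their call with an estimated correlation (camera adjusted p = 0.0236, 0.0275 and 0.0236). Of the estrogen-lowered genes BIK and EFNA1 were higher among 20, with 8 called when adjusted over the list alone, all higher (median 0.36, adjusted p = 2e-06, but adjusted p = 0.101 with an estimated correlation). Of the estrogen-induced genes CCND1 (cyclin D) was higher and SLC7A5 lower among 37, with 15 called when adjusted over the list alone, 5 higher and 10 lower (median -0.12, adjusted p = 0.0465, and adjusted p = 0.238 with an estimated correlation). That call held without E2 array 2 of control siRNA and without E2 array 1 of ERK5 siRNA, and was lost without any of the other arrays, with adjusted p from 0.0822 without vehicle array 1 of ERK5 siRNA to 0.113 without E2 array 1 of control siRNA. The cholesterol synthesis list (EBP lower, 4 lower when adjusted over the list alone, median -0.09, adjusted p = 0.0248) and the unfolded protein response list (no member called over all genes with limma, 6 lower when adjusted over the list alone, 9 of 24 at an unadjusted p under 0.05, median -0.15, adjusted p = 0.0248) lost their calls with an estimated correlation, with adjusted p = 0.174 and 0.434. Without E2 array 1 or 2 of control siRNA the cholesterol list had adjusted p = 0.233 and 0.0937, and without E2 array 2 of control siRNA or E2 array 1 of ERK5 siRNA the unfolded protein response list had adjusted p = 0.151 and 0.0742. MCM5, CDC45, GINS2, MAD2L1, BIK, EFNA1, CCND1, SLC7A5 and EBP lost their calls in 4 to 8 of the 8 fits that left out 1 array, with adjusted p up to 0.139.

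**Figure D2:**
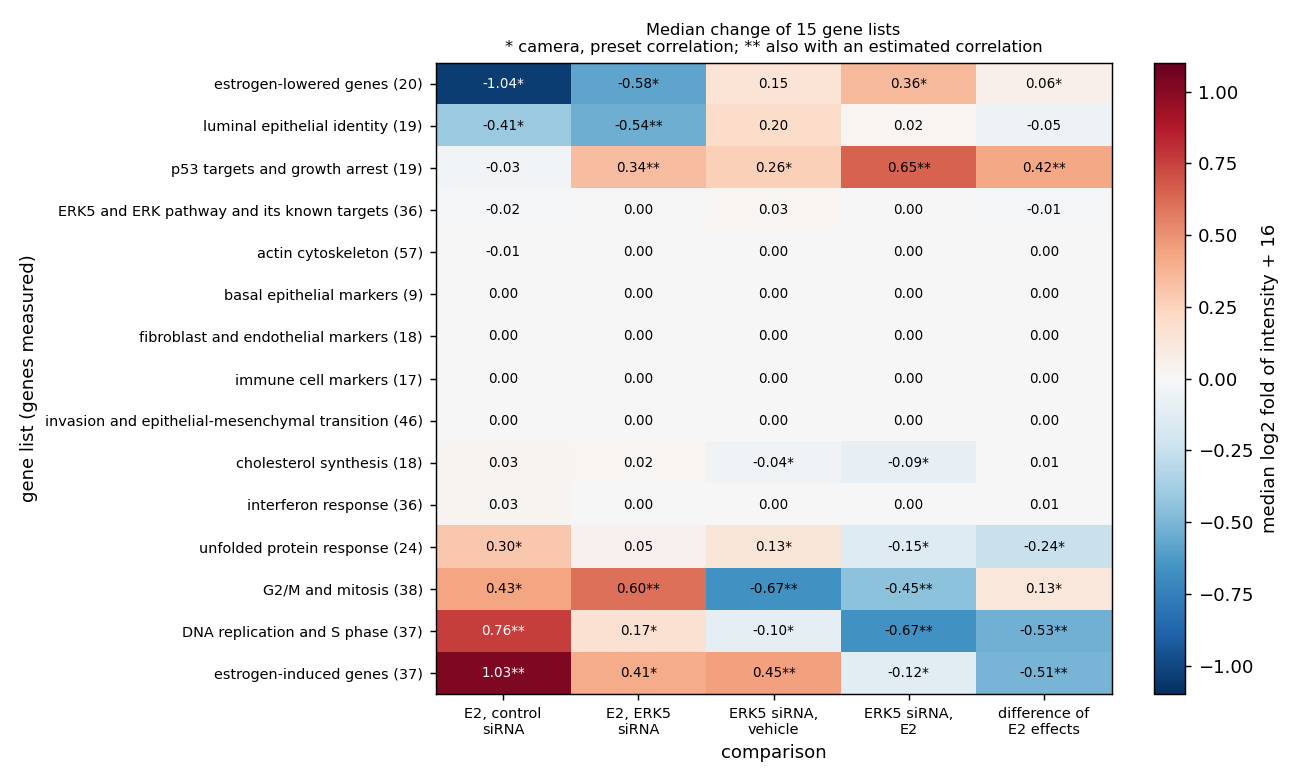
Median log2 fold of intensity + 16 (colour and number) of the 15 gene lists, with the number of genes measured, in 5 comparisons; asterisks mark lists called by camera as the title says. The DNA replication list has medians of 0.76 and 0.17 for E2 with control and ERK5 siRNA, and the p53 list is highest, at 0.65, for ERK5 siRNA with E2.

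The difference between the E2 effects was tested directly. TFF1 rose with E2 with control siRNA but had means of 5874 with vehicle and 4137 with E2 with ERK5 siRNA (difference -3.12 ± 0.124 SE on the log2 scale, limma adjusted p = 0.014). MCM2 had a difference of -1.01 ± 0.065 (adjusted p = 0.0323) and NHERF1, a scaffold protein, of -0.98 ± 0.069 (adjusted p = 0.0362), with E2 raising it with control siRNA and lowering it with ERK5 siRNA. GFRA1, a coreceptor that signals through RET, had a difference of -0.84, and SOX2, NXPH4, CSAD, ST3GAL1, POLR3C and TM4SF1 had differences from -0.77 to -0.27. ID3, an inhibitor of helix-loop-helix transcription factors, had a difference of 2.20 ± 0.145 (adjusted p = 0.0324), with means of 844.9 and 419.2 with control siRNA and 293.9 and 703.6 with ERK5 siRNA (vehicle and E2). FBN2, CXCL2, SDCBP, IP6K2, H2AC6, ANXA2, CSGALNACT1, RPRM and FRY had differences from 1.72 down to 0.24. In total 28 genes were called, 14 in each direction, of which 12 had all group means below 16, near the floor, where small spreads give small p-values (FRY, at the lowest value in 3 groups and at 8.403 in the fourth, is an example). Of the 20 genes named, 7 stayed called in every fit that left out 1 array (H2AC6, CSGALNACT1, RPRM, FRY, TFF1, SOX2, NXPH4), and the others reached adjusted p up to 0.0798. MCM2, ID3 and NHERF1 lost their calls without vehicle array 1 of control siRNA (adjusted p = 0.0526, 0.0578 and 0.0646), and NHERF1 also without E2 array 2 of ERK5 siRNA (0.0553). The count rose to between 102 and 640 when any 1 array was left out, being 102 and 244 without vehicle array 1 or 2 and 115 and 128 without E2 array 1 or 2 of control siRNA, and 412 and 640 without vehicle array 1 or 2 and 194 and 124 without E2 array 1 or 2 of ERK5 siRNA. It was 133 without both arrays of low ribosomal RNA signal. The equal numbers in both directions rested on all arrays and on the choice of genes and probe sets. They became 18 probe sets higher and 31 lower with all probe sets, and 62 genes higher and 44 lower over the 5981 brightest genes. With 1 array left out, in the same order, 74 and 190 genes were higher and 28 and 54 lower, 32 and 25 higher and 83 and 103 lower, 72 and 118 higher and 340 and 522 lower, and 155 and 96 higher and 39 and 28 lower. Without both arrays of low ribosomal RNA signal 61 were higher and 72 lower.

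By list, the DNA replication genes rose less with E2 under ERK5 siRNA, with 35 of 37 differences below 0, MCM2 called and 18 called when adjusted over the list alone (median -0.53, camera adjusted p = 1.4e-19). The E2 effect on estrogen-induced genes was smaller as well, with 31 of 37 differences below 0, TFF1 and NHERF1 called and 15 called when adjusted over the list alone (median -0.51, adjusted p = 4.52e-14). Here the level in vehicle was higher, with median ERK5 siRNA effects of 0.45 in vehicle and -0.12 with E2. The DNA replication list had -0.10 and -0.67, so its smaller rise lay mainly with E2. The p53 targets rose with E2 only with ERK5 siRNA, with median E2 effects of -0.03 with control and 0.34 with ERK5 siRNA. With control siRNA 6 of 19 E2 effects lay above 0 and 13 below, and the list did not pass camera (adjusted p = 0.49). Of the 19 differences 17 lay above 0 (median 0.42, camera adjusted p = 1.17e-08). None was called over all genes with limma, with 10 at an unadjusted p under 0.05. Adjusted over the list alone 8 were called, 7 of them higher. The DNA replication, estrogen-induced and p53 lists kept their call with an estimated correlation (camera adjusted p = 0.0236, 0.0236 and 0.024). The unfolded protein response (7 lower when adjusted over the list alone, median -0.24, adjusted p = 2.06e-05), estrogen-lowered (6 higher, median 0.06, adjusted p = 0.00519) and G2/M (1 higher, median 0.13, adjusted p = 0.0107) lists lost their calls with an estimated correlation, with adjusted p = 0.232, 0.257 and 0.285. The estrogen-lowered list also lost its call without vehicle array 2 (adjusted p = 0.121) or E2 array 2 (0.0523) of control siRNA. The G2/M list also lost its call without vehicle array 2 of control siRNA (adjusted p = 0.291), E2 array 1 of control siRNA (0.0885) and E2 array 1 or 2 of ERK5 siRNA (0.0778 and 0.0771).

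The E2 responses with both siRNAs were compared in size. Over the 885 genes raised by E2 on average, the slope of the E2 log2 folds with ERK5 siRNA on those with control siRNA was 0.922 (0.834 to 1.01 when 1 array was left out), and over the 672 lowered genes it was 0.871 (0.827 to 0.935). A slope near 1 describes the size of the responses and does not show that the same genes responded. The median ratios were 0.891 (0.697 to 0.959) and 0.878 (0.506 to 1.22). The difference of these E2 effects did not pass camera with an estimated correlation (p = 0.255 for raised and 0.264 for lowered genes), which does not show that they were equal. Without both arrays of low ribosomal RNA signal the slope for raised genes was 1.122. Of 22 DNA replication genes among those raised, 21 had a smaller E2 effect with ERK5 siRNA, with medians of 0.83 and 0.24. Of 19 G2/M genes 7 had a smaller E2 effect, with medians of 0.47 and 0.56. In total 1557 genes were called for the average E2 effect, against 983 without E2 array 1 of control siRNA, 973 without E2 array 2 of ERK5 siRNA and 440 without both. More of them were lower than higher without vehicle array 1 or 2 of control siRNA (572 higher and 596 lower, and 715 higher and 724 lower) or vehicle array 1 or 2 of ERK5 siRNA (712 higher and 954 lower, and 738 higher and 1047 lower). The share of higher genes grew without E2 array 1 or 2 of control siRNA (598 higher and 385 lower, and 666 higher and 374 lower), E2 array 1 or 2 of ERK5 siRNA (663 higher and 401 lower, and 605 higher and 368 lower), and both arrays of low ribosomal RNA signal (317 higher and 123 lower).

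**Figure D3:**
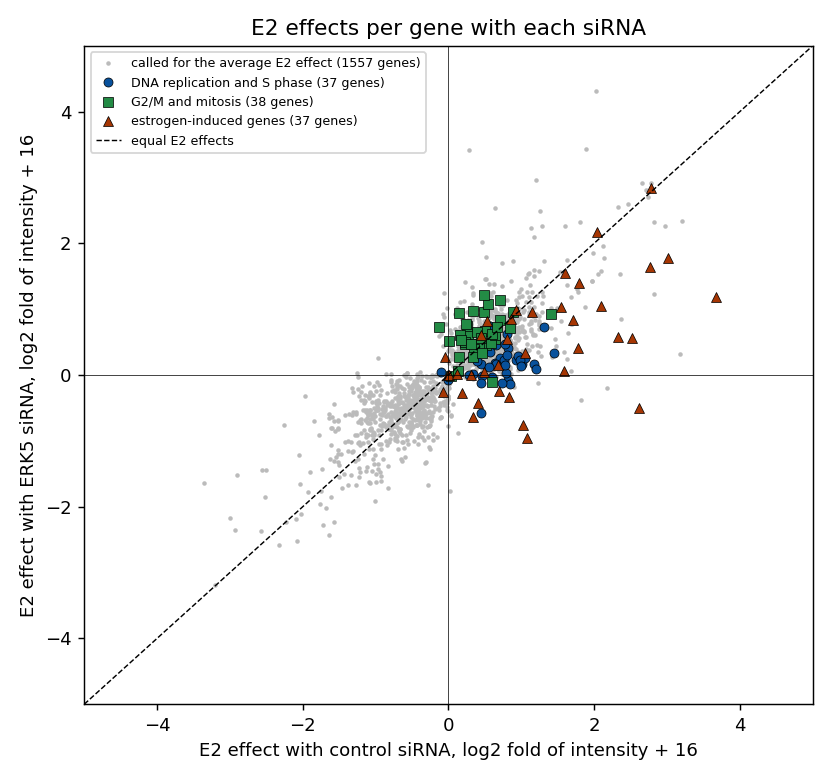
E2 effect per gene (log2 fold of intensity + 16) with control siRNA (horizontal axis) and ERK5 siRNA (vertical axis); grey points are the 1557 genes called for the average E2 effect, symbols are all measured members of 3 lists and the dashed line marks equal effects. Most DNA replication genes lie below the line, with medians of 0.76 and 0.17.

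E2 effects with the 2 siRNAs, which share no arrays, had 366 called genes in common, 205 raised and 157 lowered in both, against 47 for independent lists, out of 871 and 646 calls. The overlap was 202 without vehicle array 1, 127 and 142 without E2 array 1 or 2 of control siRNA, 134 and 127 without E2 array 1 or 2 of ERK5 siRNA, and 55 without both arrays of low ribosomal RNA signal. The log2 folds of all genes correlated at 0.724 across genes (0.679 to 0.711 when 1 array was left out). The effects of ERK5 siRNA with vehicle and with E2, which also share no arrays, had 58 called genes in common, 27 higher and 30 lower in both, against 3.65. That overlap was 33 and 34 without vehicle array 1 or 2 and 17 and 15 without E2 array 1 or 2 of control siRNA, and 13 and 10 without E2 array 1 or 2 of ERK5 siRNA. It was 0 without both arrays of low ribosomal RNA signal, where limma called no gene in vehicle (1315 at an unadjusted p under 0.05). The vehicle folds are the same in that fit, with a spread estimated from fewer arrays. The log2 folds correlated at 0.483 across genes, which are not independent replicates (0.432 to 0.489 when 1 array was left out). On average over both treatments ERK5 siRNA changed 602 genes, 250 higher and 352 lower. That count was 356 without vehicle array 1 of control siRNA, 311 and 296 without E2 array 1 or 2 of control siRNA, 1150 without vehicle array 2 and 322 without E2 array 2 of ERK5 siRNA, and 201 without both arrays of low ribosomal RNA signal. More genes were higher than lower without vehicle array 1 or 2 of ERK5 siRNA (545 higher and 296 lower, and 744 higher and 406 lower) or E2 array 1 or 2 of ERK5 siRNA (277 higher and 174 lower, and 190 higher and 132 lower). The share of lower genes grew without vehicle array 1 or 2 of control siRNA (115 higher and 241 lower, and 218 higher and 405 lower) or E2 array 1 or 2 of control siRNA (104 higher and 207 lower, and 84 higher and 212 lower), and the numbers were 101 and 100 without both arrays of low ribosomal RNA signal. The genes called for E2 with control siRNA and for ERK5 siRNA with E2 had 134 genes in common. Of these 88 rose with E2 and were lower with ERK5 siRNA, and 26 fell with E2 and were higher. These comparisons share both arrays of control siRNA with E2, so part of the excess may come from them. Independent lists would give 15.2 genes in common, a number that takes no account of the shared arrays. Across genes the log2 folds correlated at -0.387, which was no stronger than the -0.503 that shared arrays gave in 50 simulations of unchanged genes, whereas their covariance was -0.0366 against -0.00796. The overlap was 53 and 55 without vehicle array 1 or 2 of control siRNA, and 78 and 54 without E2 array 1 or 2 of ERK5 siRNA. It was 119 without both arrays of low ribosomal RNA signal.

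The actin list passed camera in no comparison, with a smallest adjusted p of 0.255 over the 5 comparisons (0.115 with fry), and none of its 57 measured members was called over all genes with limma for ERK5 siRNA with either treatment (14 at an unadjusted p under 0.05 in each). Adjusted over the list alone, 4 were called in vehicle, 3 of them higher, and none with E2. For E2 effects 4 were called when adjusted over the list alone with control siRNA and 5 with ERK5 siRNA. With control siRNA E2 lowered RHOC, a small GTPase (554.5 to 287.8), PXN (paxillin) and SSH3, a cofilin phosphatase (135.4 to 79.91), and raised GSN, gelsolin (62.12 to 138.4). These calls were also lost without arrays outside the comparison, where the fold is the same and the spread is estimated from fewer arrays. SSH3 lost its call without any 1 of the 8 arrays (adjusted p from 0.0575 to 0.0997), and GSN without each but E2 array 2 of control siRNA (0.065 to 0.123). PXN lost its call without any control siRNA array or either vehicle array of ERK5 siRNA (0.0784 to 0.13), and RHOC without vehicle array 1 or either E2 array of control siRNA or either vehicle array of ERK5 siRNA (0.0512 to 0.0712). The invasion list did not pass camera either (smallest adjusted p = 0.13, for ERK5 siRNA with E2, with 1 of 46 members called over all genes and when adjusted over the list alone, and 0.127 with fry). FN1, fibronectin, rose with E2 from 8.588 to 43.69 with control siRNA and from 7.957 to 99.14 with ERK5 siRNA, and was higher with ERK5 siRNA and E2 (0.95 ± 0.105, limma adjusted p = 0.0388), a call that was lost without any 1 of the 8 arrays (adjusted p from 0.07 to 0.129). Without probe sets of lower specificity, FN1 is represented by another probe set, with log2 folds of -0.003 for E2 with ERK5 siRNA and -0.007 for ERK5 siRNA with E2. The lists of the ERK5 and ERK pathway, interferon response, basal, fibroblast and endothelial, and immune genes did not pass camera, with smallest adjusted p of 0.255, 0.146, 0.49, 0.255 and 0.216. In the comparisons with these p-values, 1 member of the ERK5 list, 4 of the interferon list and 1 of the basal list were called when adjusted over the list alone. In the fibroblast and endothelial list none of 18 was called that way (1 at an unadjusted p under 0.05), and in the immune list none of 17 (0 at an unadjusted p under 0.05). The test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called some of these lists. The basal list passed it for E2 with control and with ERK5 siRNA (adjusted p = 0.00525 and 0.00601, both higher). The interferon list passed it for E2 with ERK5 siRNA (0.00314, higher), ERK5 siRNA in vehicle (0.0173, lower) and the difference (0.0221, higher). The immune list (0.0495, lower) and the ERK5 list (0.0446, higher in fry but lower in camera) passed it for E2 with ERK5 siRNA. Among lists called by camera elsewhere, fry also called cholesterol synthesis for E2 with control siRNA (0.0253, higher) and luminal identity for ERK5 siRNA in vehicle (0.0446, higher), which camera did not (0.519 and 0.146).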

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

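The tests of explanations in the 3 paragraphs on DNA replication, estrogen-induced and p53 target genes were chosen after results that bear on them had been seen. So was the comparison of shared calls with independent lists. The tests of the difference and the counts of splits were planned.

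What marks these results is a difference between the siRNAs in the effect of E2, tested directly. It was called for 28 genes, of which 12 had all group means below 16, near the floor. Over the 5981 brightest genes 11 of the 28 stayed called. With the replicate number as a block limma called 2 genes. The largest difference fell on TFF1 (-3.12), followed in that direction by MCM2 (-1.01), NHERF1 (-0.98), GFRA1 (-0.84), SOX2 (-0.77), NXPH4 (-0.55), CSAD (-0.5), ST3GAL1 (-0.47), POLR3C (-0.42) and TM4SF1 (-0.27), on the log2 scale. In the other direction lay ID3 (2.2), FBN2 (1.72), CXCL2 (1.56), SDCBP (1.3), IP6K2 (1.23), H2AC6 (1.04), ANXA2 (1.01), CSGALNACT1 (0.61), RPRM (0.35) and FRY (0.24). The lists whose difference also held with an estimated correlation were DNA replication (median -0.53), estrogen-induced genes (-0.51) and p53 targets (0.42). The unfolded protein response (-0.24), estrogen-lowered (0.06) and G2/M (0.13) lists differed at the preset correlation and not with an estimated one (adjusted p = 0.232, 0.257 and 0.285).

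DNA replication genes rose less with E2 under ERK5 siRNA. A weaker response of all genes would lower other E2-raised genes alike, but their median ratio of E2 effects was 0.904 over 863 genes (0.857 to 0.93 when 1 array was left out), against 0.246 for the list (0.187 to 0.334). Without both E2 arrays of low ribosomal RNA signal the median difference of the list was -0.579, against -0.531 with them, so that signal does not account for it. A smaller gain in cycling cells would lower the G2/M genes as well, but their median difference was 0.126 (0.114 to 0.173). That difference starts from a lower level, as the G2/M list had median ERK5 siRNA effects of -0.67 in vehicle and -0.45 with E2. The DNA replication list had -0.10 and -0.67. Both lists were thus lower with ERK5 siRNA and E2, so this test does not settle whether fewer cells were cycling. A hypothesis that stays open is that the E2 response of replication genes depends on ERK5, which may be untrue if the siRNA acts on other transcripts, since MAPK7 reached only 7.14.

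Estrogen-induced genes were higher in vehicle under ERK5 siRNA. E2 in those cultures would move all E2-responsive genes. But over 1557 of them the slope of the ERK5 siRNA effect in vehicle on the average E2 effect was -0.0444 (-0.0539 to -0.0262). Vehicle and E2 arrays of ERK5 siRNA exchanged would cancel the average E2 effect, so this slope cannot test an exchange. An exchange would also give E2 folds of opposite sign with the 2 siRNAs. Across genes these folds correlated at 0.724, which argues against it. A trace of E2 that reaches only the most sensitive genes was not tested. An effect of the siRNA other than on MAPK7 cannot be told apart from loss of ERK5, because MAPK7 reached only 7.14 and a single siRNA product is named.

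p53 target genes were higher under ERK5 siRNA, with E2 also by an estimated correlation and in vehicle only at the preset correlation. In vehicle an interferon response to the siRNA would raise interferon genes, but the 14 list members with a mean intensity of at least 16 had a median ERK5 siRNA effect of -0.28 (-0.328 to -0.128). With E2 the median was 0.127 (-0.00502 to 0.254), which leaves that explanation open there. An action of the siRNA on other transcripts stays open as above.

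Other splits of the 8 arrays into 4 and 4 were compared with both average effects in a fit of 2 groups. For E2 the real split called 676 genes and the highest other 15, and 1 of 35 splits reached the real value. That is the smallest share 35 splits allow, and other splits leave the E2 effect in the spread, so the count cannot exclude chance. For ERK5 siRNA the real split called 15 genes and 2 of 35 splits reached that, itself included, so this count alone does not exclude chance. The other such split was E2 against vehicle, with 676 genes, a structure of the samples that the design names. The siRNA effects in vehicle and with E2, which share no arrays, had 58 called genes in common, 27 higher and 30 lower in both, against 3.65 for independent lists. That overlap was 10 without E2 array 2 and 78 without vehicle array 2 of ERK5 siRNA (1.03 and 12.2 for independent lists). It was 0 in 3 fits in which limma called 0 or 1 gene for one of the effects. These were the fits without both arrays of low ribosomal RNA signal, with only the arrays compared and with the replicate number as a block (1315, 1315 and 1593 genes at an unadjusted p under 0.05 for that effect). For ERK5 siRNA in vehicle the first 2 of these are the same fit, as both take the spread from the vehicle arrays alone. The correlation of the log2 folds across genes was 0.483 (0.432 to 0.489 when 1 array was left out, and 0.472 without both low arrays). Simulations of unchanged genes gave 0.000393 on average. They drew each gene's noise independently, so a value this small was fixed by their setting and the comparison does not exclude chance.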

How the results depend on the processing

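The fits without pseudocount and without both E2 arrays of low ribosomal RNA signal were chosen after seeing the data. Counts are given in the order E2 with control siRNA, E2 with ERK5 siRNA, ERK5 siRNA in vehicle, ERK5 siRNA with E2, difference, average E2 and average ERK5 siRNA. Keeping only the 5981 brightest genes gave 1630, 1318, 639, 712, 106, 2347 and 1406, with 740 of the 871 calls for E2 with control siRNA kept. Of the 28 calls for the difference, 14 were among these genes and 11 stayed called. The prior degrees of freedom rose there from 0.44 to 5.53. Keeping only the 8972 brightest gave 1349, 1032, 476, 498 and 60 for the first 5 and 1094 for the last. Without probe sets of lower specificity the counts were 444, 274, 97 and 78 for the first 4 and 780 and 251 for the averages. With equal medians they were 316, 345 and 67 for ERK5 siRNA in vehicle, with E2 and the difference. With only the arrays compared, which leaves fewer degrees of freedom, they were 118, 52, 0 and 14 (1315 genes at an unadjusted p under 0.05 beside the 0 of limma). Without both low arrays they were 204, 148, 0, 195, 133, 440 and 201, and the slope for raised genes was 1.122. The difference count was 49 with all probe sets, 47 with the mean of probe sets, 60 with trend and robust, 46 and 44 with pseudocounts of 1 and 64, and 47 with none. The equal directions of the difference became 36 higher and 31 lower with equal medians, 18 and 31 with all probe sets, 22 and 25 with the mean of probe sets, 9 and 12 without probe sets of lower specificity, 21 and 25, 20 and 24, and 22 and 25 with pseudocounts of 1, 64 and none, and 62 and 44 over the 5981 brightest genes. More genes turned lower than higher for E2 with ERK5 siRNA with quantile normalization (315 higher and 319 lower) and only the arrays compared (25 and 27). For ERK5 siRNA with E2 more turned higher with all probe sets (76 and 74 probe sets) and only the arrays compared (8 and 6 genes). Counts of at least 2-fold changes for the first 4 comparisons were 153, 109, 33 and 33 with a pseudocount of 64, 154, 98, 31 and 22 without probe sets of lower specificity, and 39, 29, 0 and 10 without both low arrays (the 0 with limma, where 1315 genes had an unadjusted p under 0.05). The overlap of 134 genes was 221 with equal medians, 50 without probe sets of lower specificity, 327 and 444 over the 8972 and 5981 brightest genes, and 0 with only the arrays compared. Of 160 calls of named genes 69 held in every fit that left out 1 array. Of 31 list calls 13 held with an estimated correlation and in every other setting tried. Some of these fits lacked only arrays outside a comparison, which keeps its folds and changes only the estimate of the spread. So it was for ERK5 siRNA in vehicle without both low arrays. Beyond fewer arrays or genes, the cause was not tested.

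Arrays of equal replicate number showed little or no shared deviation, as correlations of the deviations (array 1 minus array 2) lay between -0.226 and 0.0565. Whether equal numbers were handled together is not stated in the labels, and these values do not settle it. The lowest was between the 2 E2 groups. There arrays of unlike number deviated partly alike. Array 1 of control siRNA and array 2 of ERK5 siRNA had the low ribosomal RNA signal, and a link between both was not tested. With the number as a block the counts were 382, 262, 66, 1, 2, 1033 and 199, and the overlap was 0.

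With 1 array left out, where a lone array is assumed to vary like the other groups, the counts ranged from 377 to 821, 305 to 1082, 45 to 906, 88 to 315, 102 to 640, 973 to 1785 and 296 to 1150, and the overlap from 53 to 163. Calls shared with the fit of all arrays were 261 to 459 of 871 and 39 to 172 of 209 for E2 with control siRNA and ERK5 siRNA in vehicle, and no called gene changed sign. MAPK7 ranged from -0.0396 to -8e-04, with a call only without vehicle array 1 of control siRNA. Uncalled values that changed sign were those of CFL1 for the difference (-0.003 with equal medians, -0.036 without both low arrays, -0.123, -0.041, -0.019 and -0.005 without 1 array, in a range up to 0.124) and in vehicle (-0.071 to 0.176), and of ESR1 for the difference (-0.03 and -0.001 without 1 array, in a range up to 0.175) and in vehicle (-0.103 with the mean of probe sets). FN1, called, had -0.003 and -0.007 without probe sets of lower specificity.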

Other observations

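The tests of this part were written before their results were seen, after the genes named at the head of each paragraph had been seen. ID1, ID3, NHERF1 and XBP1, chosen after their values were seen, are the 4 genes called for E2 with both siRNAs in opposite directions. With E2, ID1 fell by 1.39 on the log2 scale with control siRNA and had a log2 fold of 1.16 with ERK5 siRNA, and ID3 had log2 folds of -0.99 and 1.21. NHERF1 had log2 folds of 0.33 and -0.64, and XBP1, a transcription factor of secretory cells, 0.41 and -0.42. The test of the difference itself gave adjusted p = 0.053 for ID1 and 0.0573 for XBP1 with limma, which do not pass.

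SLC7A11, SLC7A5, SLC1A4, PCK2 and NUPR1 are known targets of ATF4, the transcription factor of the amino acid response, and were all lower with ERK5 siRNA and E2 than with control siRNA and E2. The hypothesis that ATF4 targets respond as a class was tested on 25 other measured targets (tRNA synthetases, serine synthesis and transport genes). For the E2 effect with control siRNA, 10 of them were called higher and none lower, among them PSAT1, SHMT2, MTHFD2 and GARS1. For the E2 effect with ERK5 siRNA their median log2 fold was 0.0669, against 0.732 with control siRNA. All 25 differences of E2 effects lay below 0, with a median of -0.689 (-0.732 to -0.538 when 1 array was left out), but camera with an estimated correlation gave adjusted p = 0.0604 over the 10 tests of these added lists (p = 0.0175 unadjusted), against adjusted p = 3.57e-15 at the preset correlation and 0.00627 with fry. By the rule set beforehand this does not pass, and the hypothesis stays open.

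CXCL8, CCL2, CCL20, CXCL1, CXCL2 and CXCL10 are targets of NF-kB. The hypothesis that NF-kB targets respond as a class was tested on 22 other measured targets. CXCL3, NFKBIA, PTGS2 and TNFAIP3 were called higher for the E2 effect with ERK5 siRNA, and none of the 22 with control siRNA by limma (3 at an unadjusted p under 0.05). The median difference of E2 effects was 0.011 (0.00487 to 0.0216), with 18 of 22 above 0. Camera with an estimated correlation gave adjusted p = 0.0604 (p = 0.0325 unadjusted), against adjusted p = 0.00112 at the preset correlation and 0.0264 with fry. By the same rule this does not pass, and the hypothesis stays open. Many members lie near the floor of the arrays.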
